A study of Bacillus subtilis subsp. subtilis str. 168 with 14 samples.

How the data were processed

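RNA of 14 samples of Bacillus subtilis 168 was measured on 28 two-colour arrays. Per the file headers, spots were read on an Agilent scanner and quantified with ArrayVision as intensity, with a local background intensity, a signal-to-noise score and the percent of pixels at the scanner's ceiling, and no normalization is recorded there. Per the labels, Cy3 held the sample and Cy5 the vegetative reference in every array, without a dye swap. The authors' deposited value table holds, per the labels, the median of 4 normalised Cy3 values (2 spots on 2 arrays). It is an intensity on a linear scale for 4008 genes. Its normalization method and scaling stay unknown, and its medians ran from 64.3 at 5 min to 426.4 at 40 min, with 77.6, 306.2, 228.4, 250.7, 328.1, 236.8, 299.3, 338.0, 286.3, 260.0, 289.1 and 320.6 at 0, 10, 15, 20, 25, 30, 50, 60, 70, 80, 90 and 100 min.

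The log2 ratio of Cy3 over Cy5 was computed with limma 3.58.1 in R 4.3.3, with normexp background correction (offset 50) and loess within each array, control spots weighted 0. Duplicate spots were averaged, then arrays A and B, which are technical replicates of 1 sample. Probes were kept when the signal-to-noise score exceeded 2 on at least 3 of the 4 spots in at least 3 germinated samples, which left 4082 of 4100. Of 4100 probes, 4032 matched the gene table through their locus number, and 1026 took a newer name from it.

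Window means were compared in 1 limma fit of all 14 samples, with calls at an adjusted p under 0.05 (Benjamini-Hochberg) and an absolute log2 change of at least 1. The time course was a natural cubic spline with 3 df and limma's moderated F. Gene lists (38, with at least 5 measured members) were tested with camera at a preset correlation of 0.01 and again with the correlation estimated. Dormant spores against 5 min is 1 sample against 1 and has no p. The windows, tests, lists and alternatives were fixed before the data were examined, as was the rule for named genes: the 12 largest changes each way for late against early and 6 each way for the other contrasts, among called genes with the same direction in arrays A and B alone; the 6 smallest p-values of the time course; the 15 detected probes with the largest and the 10 with the most negative dormant differences and the 15 brightest dormant probes; and the 4 members with the largest change in each list called by camera. Of these, the text names a part, and list members mainly where the list held a called gene. On simulated data with 200 changed genes among 4082, late against early recovered 76% of changes of 1.5 and 96% of changes of 3 on the log2 scale, and the time course recovered 53% and 79%. The simulation drew independent normal noise per gene around a flat mean and put a step into the late window alone. Genes of these data are correlated and drift within windows, so these shares are not the power of this series.

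The table was planned as an alternative to the scanner files and is one here. That the files and the table place most samples at different times was found after the data were examined. The table was then tried as the main source, and the arrays were also tried at the table times they matched. Both were set aside: the planned source was kept because results from both had already been seen, and a sample's time is not taken from its values. Counts from the table are given with each result for which it holds values, and results from the moved arrays are not used. Alternatives for single genes were limited, after their number had been seen, to the largest changes and to members of called lists holding a called gene. The genes named for the time course were not recomputed under alternatives. Forms of the table with 50 added or quantile normalization, the slide series, the runs without 30, 40 and 50 min and further detection limits were also chosen after seeing the data. Slides fell into 2 series by their numbering, which both hybridisations and all windows of germinated samples shared. Arrays A and B of a sample had a residual correlation of 0.528.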

Results

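Transcript levels were followed in Bacillus subtilis 168, a soil bacterium that forms dormant spores, while spores germinated and grew out. One RNA sample came from dormant spores and 13 came from 5 to 100 min after the start of germination. Each sample was labelled with Cy3 and hybridised together with Cy5-labelled RNA of vegetative cells, the common reference, on 2 spotted oligonucleotide arrays (A and B) carrying 4100 gene probes. With 1 sample per time point there were no biological replicates, so neighbouring times stood in for them: early (5, 10 and 15 min, n = 3), middle (20, 25 and 30 min, n = 3), advanced (40, 50 and 60 min, n = 3) and late (70, 80, 90 and 100 min, n = 4). The p-values measure the spread between these times, and the number of arrays limits the precision. No genome coordinates were used. Locus numbers are those of the array's annotation.

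The time labels of the scanner files and of the authors' value table did not match. Across genes, the table's columns for 0 and 5 min correlated best with the arrays filed under 0 and 5 min (Spearman rho 0.994 and 0.969). Arrays filed under 10, 15, 20 and 25 min correlated best with the table's 70, 80, 90 and 100 min (rho 0.990, 0.993, 0.999 and 0.998). Those filed under 60, 70, 80, 90 and 100 min correlated best with the table's 10, 15, 20, 25 and 30 min (rho 0.998, 0.994, 0.990, 0.998 and 0.999). Arrays filed under 30, 40 and 50 min were no column's best match. In turn, the table's 40, 50 and 60 min were no arrays' best match, with a highest rho of 0.910, 0.909 and 0.956. These correlations are across genes, which are not independent replicates. Every comparison below was fitted to the scanner files under the samples they are filed with, as planned. Counts from the authors' table stand beside those for which it holds values, and table values are given for a part of the named genes and lists. Windows therefore name arrays "filed under" a time, and no direction below is settled where the sources oppose each other.

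**Figure D1:**
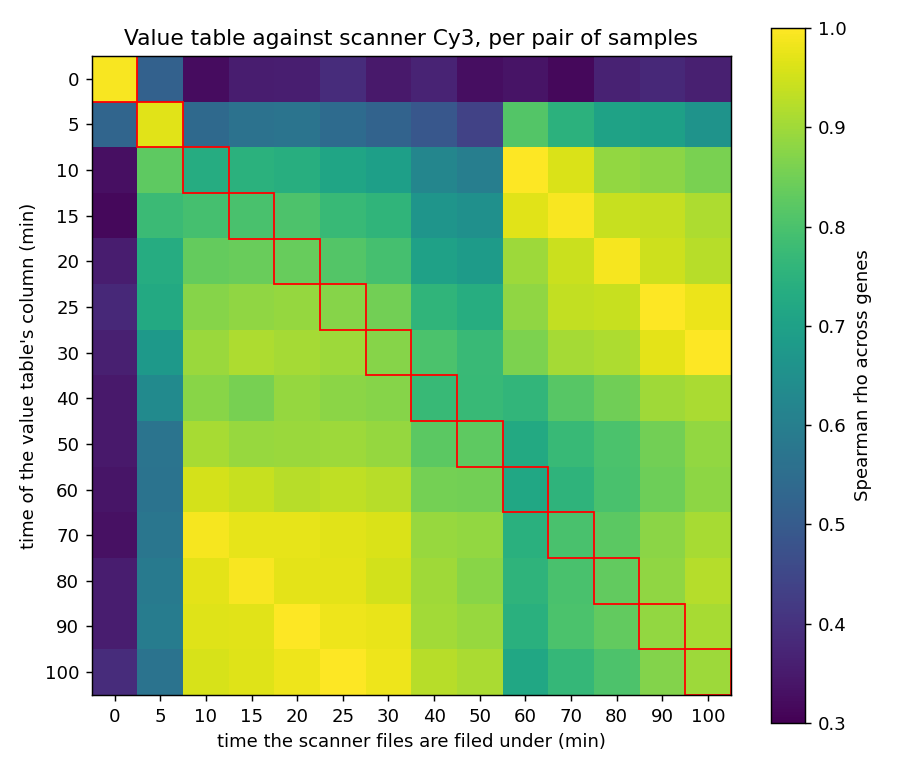
Spearman rho across genes between each column of the authors' value table (vertical axis, labelled time in min) and the mean Cy3 level of each pair of arrays (horizontal axis, time in min under which the files are deposited). Red squares mark equal times. Only 0 and 5 min are the best match there, at 0.994 and 0.969.

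In dormant spores 22 of 4100 probes (0.537%) exceeded the 95th percentile of empty and negative control spots on both arrays, against 158 at 5 min. Of these 22 probes 7 belonged to the 18 of the list of small acid-soluble spore proteins. Intensities of different probes are not on a common scale of abundance. The probe with the highest intensity was that of ykzE (BSU13510), with Cy3 intensities of 14536 and 13745 on arrays A and B. Next came sspE (BSU08660) at 12790 and 14903, sspN (BSU18020) at 12470 and 9638, yfhD (BSU08490) at 12436 and 9100, and yqfX (BSU25080) at 10789 and 9893. The spore protein genes sspJ, sspO, sspP and sspT were also among the 15 with the highest intensity. The limit set this count: with empty spots alone 3549 probes passed, and with negative control spots alone 9 passed. It also set the order against 5 min, where 3418 passed with empty spots alone. With the local background 3845 passed in dormant spores and 3809 at 5 min.

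The comparison of dormant spores with 5 min asked what changed first, and it had no replicate check. The log ratio differed by at least 1 on both arrays for 291 of 4082 probes, 151 higher in dormant spores and 140 lower. The differences on array A and on array B had a Pearson r of 0.64. Arrays A and B of 5 min had the lowest Cy3 correlation of all samples (Pearson r 0.873). The 10 probes with the most negative difference were not detected in dormant spores and were detected at 5 min, so the size of their differences is not given. They included hrcA (BSU25490), the repressor of heat-shock chaperone genes, clpE, a heat-inducible protease subunit, and guaB, an enzyme of GMP synthesis. At 5 min the Cy3 intensity of hrcA was 4841 and 4853 on arrays A and B, while the detection limits of the dormant arrays were 700 and 548. Small acid-soluble spore proteins had a median difference of 1.74, where the central 95% of 10000 random lists matched on mean level ended at 0.23. Of the 18 members of this list 7 were higher by at least 1 on both arrays. The list's median was 1.34 with median centring, 1.15 with quantile-normalised Cy3, 0.91 with Cy3 scaled to the 75th percentile and 0.83 in the authors' table, where the median of all genes was 0.31. The gene sspE differed by 3.15 in the normalised ratio, while its Cy3 intensities at 5 min, 11528 and 13783, were close to the dormant ones. Of the 151 higher probes, 15 were detected in dormant spores, and of these 15 none stayed higher by at least 1 on both arrays with median centring, 2 did with quantile-normalised Cy3 and 2 with Cy3 scaled to the 75th percentile, and 7 were higher by at least 1 in the authors' table. The random lists were drawn gene by gene, whereas members of a gene list can be correlated, so their central range may be too narrow. Of 38 lists, 15 lay above the central range of their random lists and 4 below. Ribosomal proteins were among the former at 0.88, with no member detected in dormant spores, but lay at -0.58 with median centring, at -0.20 with Cy3 scaled to the 75th percentile, at 0.24 with quantile-normalised Cy3 and at -0.63 in the table. Heat-shock genes at -0.78 and DNA replication genes at -0.65 were among the latter, and both were also negative under these scalings and with quantile-normalised Cy3. The split depended on scaling, with 16 higher and 112 lower after median centring, 24 and 96 with Cy3 scaled to the 75th percentile, 512 and 543 with quantile-normalised Cy3 and 241 and 392 without background correction. The authors' table, which holds 1 value per gene and sample, gave 428 higher and 574 lower. Array A alone gave 289 higher and 510 lower, array B alone 334 and 157, and the early window in place of 5 min gave 285 and 76.

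Between the early and the middle window no gene passed the threshold in limma with Benjamini-Hochberg adjustment, and 144 of 4082 had an unadjusted p under 0.05. The authors' table gave 81 calls, 73 higher and 8 lower. Gene groups were compared with camera, which sets a list against all other genes. With a preset correlation, 6 lists lay higher and 4 lower in the middle window, all of them without a called member. The pyrimidine synthesis list had a median 0.97 above that of all genes (adjusted p = 0.00102), and the small acid-soluble spore proteins lay at -0.45 (adjusted p = 0.00462). None of these calls held with an estimated correlation (adjusted p = 0.862 for both). In the table the spore proteins lay at -1.17 and the pyrimidine list at -0.32, the opposite sign. Without 5 min the spore protein shift was 0.01.

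Between the middle and the advanced window 1 gene was called, ganS, which rose by 1.45 ± 0.18 (SE, adjusted p = 0.0302), whereas it differed by 0.01 in the table. The table gave 101 calls, 100 higher and 1 lower. By camera, 4 lists were higher and 9 lower, and none held with an estimated correlation, for which the lowest adjusted p was 0.589. Ribosomal proteins lay 0.36 below all genes in the scanner files (median shift -0.36) and at -1.29 in the table. The general stress genes under SigB lay at -0.32 in the scanner files (0.20 without 60 min) and at 1.73 in the table, and purine synthesis at -0.81 and 2.80. No arrays correlated best with the advanced columns of the table, so its values here have no matched arrays for that window. The count rested on single times: it was 198 without 60 min and 0 without 20, 25, 30, 40 or 50 min. It was 0 with slide series as a covariate. It was 0 on series 1, which holds no array of 25 or 40 min, and 390 on series 2, which holds none of 60 min, so that series and times changed together. With only the compared windows fitted, ganS was not called and the 1 call was rplJ, which fell by 2.06 and was named after its value was seen.

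Between the advanced and the late window 179 genes were called, 66 higher and 113 lower. Purine synthesis genes, which make AMP and GMP precursors, had 12 of 16 members lower and none higher (14 adjusted over the list alone). Among them purL (BSU06480) fell by 3.38 ± 0.80 (SE, adjusted p = 0.0338) and purQ fell by 3.26 ± 0.73. Of 53 ribosomal proteins 12 were higher and 1 lower (15 and 1 adjusted over the list alone), with rplJ (BSU01040) higher by 2.83 ± 0.36 (adjusted p = 0.00408) and rpsP by 1.62 ± 0.19. Of 15 heat-shock genes 6 were lower, among them groES, a chaperonin subunit, which fell by 3.13 ± 0.72, and groEL, which fell by 1.88 ± 0.38. Of 69 catabolite-repressed degradation genes 14 were lower (32 adjusted over the list alone), including rocG and rocE of arginine degradation, which fell by 3.74 ± 0.98 and 3.30 ± 0.79. Of 45 flagella and chemotaxis genes 3 were lower (27 adjusted over the list alone). The oligopeptide transporter gene oppA fell by 4.32 ± 1.10, and yocC, ykwD and ykoJ rose by 3.27, 2.96 and 2.88. Camera called 5 lists higher and 8 lower, none of them with an estimated correlation, for which the adjusted p of the purine, ribosomal, heat-shock, degradation and flagella lists was 0.469.

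The authors' table gave 1 call for the same windows, and 82 of the 176 genes called from the scanner files that it holds had the same sign there. Its single-gene values are not centred, and the median of all genes was -0.32 there. It had purL higher by 1.06 and rocG by 0.78, neither of them called. Ribosomal proteins lay higher in both sources, at 0.76 in the scanner files and 0.98 in the table, while the purine list lay at -2.87 and 1.38 and the citric acid cycle at -3.73 and 1.29. The count from the scanner files was 1056 without 60 min, and 28, 23, 101, 55, 29 and 82 without 40, 50, 70, 80, 90 and 100 min. Without 60 min 368 were higher and 688 lower, while each of the other 6 omissions left more genes higher than lower, with 22 and 6, 17 and 6, 54 and 47, 34 and 21, 21 and 8, and 53 and 29 in that order. The excess of lower genes among the calls was therefore lost without any 1 of these 6 times. Counts of calls do not show whether the differences themselves changed. With slide series as a covariate 186 were called. Series 1 alone gave 2 and series 2 alone, which holds no array of 60 or 100 min, gave 1421, so that series and times changed together. Leaving out 30, 40 and 50 min, a setting chosen after seeing the data, leaves 60 min as the only advanced sample, so its count of calls is not given.

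The late against the early window spanned the whole course and gave 113 calls, 44 higher and 69 lower. Of 16 purine synthesis genes 14 were lower, also when adjusted over the list alone. purL fell by 3.81 ± 0.80 (SE, adjusted p = 0.0268), with a log2 ratio to vegetative cells of -3.49 ± 0.32 (SD, n = 4 times) in late and 0.31 ± 1.61 (SD, n = 3) in early arrays, each late value below each early one. purN, purQ, purH, purM, purS, purF, purC, purD and purA fell by 3.78, 3.72, 3.65, 3.61, 3.59, 3.53, 3.40, 3.31 and 3.22. Of 19 sulfur amino acid genes 9 were lower, including cysC, cysP and sat of sulfate assimilation, which fell by 3.27, 3.21 and 3.12, and sumT, which fell by 3.39. The chaperonin genes groES and groEL fell by 2.81 and 1.92, comS and nucA of the competence list by 2.58 and 1.68, and serS, seryl-tRNA synthetase, by 1.74. Rises included yocC at 3.57 ± 0.81, yocD at 3.15, queE and queF of queuosine synthesis at 2.62 and 2.48, yhcU at 2.08, ypmS at 1.92, ypmT at 1.79, ypzK at 1.65, yojO at 1.60, yccF at 1.49, dinF at 1.48 and abrB, a transition state regulator, at 1.48. Of 53 ribosomal proteins 5 were higher (13 adjusted over the list alone), such as rpmB at 1.32 and rpmGA at 1.29, and of 24 SOS and repair genes 1 was, addA at 1.20. Camera called 8 lists higher and 10 lower, none with an estimated correlation (adjusted p = 0.418 for the purine list).

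For the same windows the authors' table gave 1010 calls, 920 higher and 90 lower, with the median of all genes 0.74 higher. No gene was called in the same direction by both sources and 54 were called in opposite directions. Of the 112 genes called from the scanner files that the table holds, 19 had the same sign there. Single-gene values of the table are not centred on its shift of all genes, so these signs do not share a zero with the scanner ratios. Across genes the differences had a Pearson r of -0.58 and a Spearman rho of -0.62. In the table yocC was lower (-2.50, not called), purL was higher by 4.57 (adjusted p = 0.0114), cysC by 5.00 (adjusted p = 3.34e-04), groES by 2.36 and comS by 3.60. Relative to all genes, the purine list lay at -3.32 in the scanner files and 3.53 in the table, the citric acid cycle at -2.15 and 2.93, and flagella and chemotaxis at -1.19 and 1.29. Ribosomal proteins lay at 0.76 and 1.04, the latter without a call by camera (adjusted p = 0.706). Leaving out 10 min ended all calls from the scanner files, and 67, 24, 36, 26, 36 and 81 were left without 5, 15, 70, 80, 90 and 100 min. Median centring in place of loess left 0, Cy3 alone scaled to the 75th percentile 0 and Cy3 alone with quantile normalization 5. With slide series as a covariate 196 were called. Series 1 alone gave 18. Series 2 holds 10 min as its only early sample, so its count of calls is not given.

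**Figure D2:**
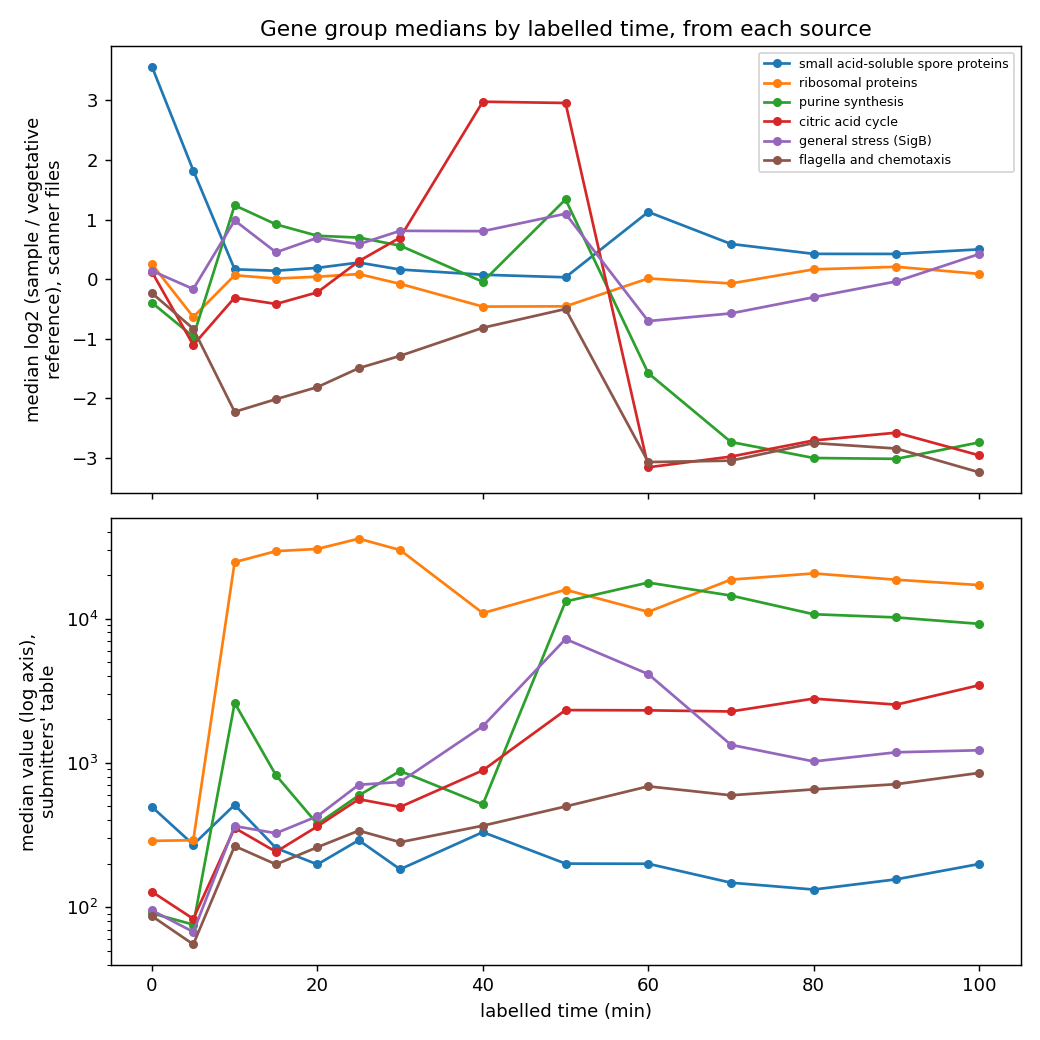
Median over the genes of 6 groups against labelled time (min), from the scanner files (upper panel, log2 ratio of sample to vegetative reference) and the authors' value table (lower panel, normalised Cy3 intensity on a log axis). Each point is 1 sample. In the scanner files the purine synthesis median is 1.24 at 10 min and -2.74 at 100 min, and in the table it is 2598 at 10 min and 9185 at 100 min.

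A spline over the 13 germinated samples asked which transcripts followed a smooth course. It called 883 of 4082 genes (21.6%), and the smallest adjusted p-values belonged to yxlC, mreBH, aroX, yxlF, walL and yxlD. By filed time, fitted maxima lay most often at 25 min (178 genes), 5 min (147 genes) and 70 min (137 genes). Arrays filed under 25 and 70 min correlated best with the table's 100 and 15 min, so these maxima are not settled in time. No maxima from the table are given. The table gave 1430. Leaving out 70, 80, 90 or 100 min lowered the count to 317, 346, 316 and 351. The spline with 2 df gave 204 and that with 4 df 1542, and array A alone gave 496.

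Against the vegetative reference, which counts as 1 control sample without its own spread, 877 genes differed in the late window, 332 higher and 545 lower. No dyes were swapped, so gene-specific dye bias remained. The flagellin gene hag fell by 6.71 ± 0.66 (SE, adjusted p = 4.86e-05), yolA fell by 5.16, comS fell by 5.04, the cell wall protease gene wprA fell by 4.99 and the surfactin synthetase gene srfAB fell by 4.90. ykvT was higher by 5.39 ± 0.65 (adjusted p = 9.20e-05), ybcH by 4.90, ybcF by 4.65, ykwD by 4.16 and ybcD by 3.80. The table holds no reference values, and the late window here means arrays filed under 70 to 100 min, which correlated best with the table's 15 to 30 min.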

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

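All tests of explanations in this part were chosen after the result was seen. No group median stood apart within the late window: none of 38 lists had a time whose gap to the others, as a share of the range, exceeded Dixon's critical value, where chance would give about 1.9.

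The scanner files and the value table disagree about which time most samples belong to. The authors' normalization is argued against as the cause, since only 2 of 14 table columns were closest to the arrays filed under their own time. Files attached to other samples are a candidate explanation: 9 of the 12 pairs filed under 10 to 100 min matched another time's column mutually, at a rho of 0.990 or more. Random orders cannot decide which source carries the right times, because the matched pairs moved in blocks that keep neighbouring times together. Of 10000 random orders, 0 were as smooth as the table's and 13 as smooth as the files'. Both sources agree on 5 min. The table's 5 min column had a rho of 0.660 to 0.812 with arrays filed under 60 to 100 min. With arrays filed under 10 to 50 min it was 0.439 to 0.570. These values go with the table's times if neighbouring times are the most alike, but they rest on 1 sample. The table's order was the smoother one, with a mean rho between neighbouring times of 0.943 (lowest 0.811) against 0.897 (lowest 0.570) for the files. The table's values are medians over arrays after the authors' normalization. Mutually matched arrays and columns had a rho of 0.990 or more, except those of 5 min at 0.969. Where it was 0.990 or more, the normalization changed the order of genes little. No biological explanation was tested.

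Of 151 probes with a higher ratio in dormant spores than at 5 min, 136 were not detected in dormant spores. Whether loess within arrays on which most probes lie near background accounts for the higher ratios cannot be told apart from real differences. Of 4 settings without the loess step used here, 2 left a minority of the 151 higher, 15 with median centring and 24 with Cy3 scaled to its 75th percentile. The other 2 left a majority, 122 with quantile-normalised Cy3 and 93 in the authors' table. These carry a normalization of their own, and that of the table is unknown, so it may itself include a loess step. The table's count needed a single difference of at least 1, not centred on its median of 0.31 for all genes. The other settings needed a difference of at least 1 on both arrays, so the counts are not on equal terms. Of the ribosomal protein genes, 16 were among the 151 and 0 were detected in dormant spores. Real differences in weak transcripts stay open.

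Other splits of the samples into windows were compared by their number of calls. For late against early (113 calls), 1 of 35 splits, the real one, gave as many, and the highest other gave 0 calls. The samples are single ordered times and not exchangeable replicates, so a split by time can stand out and chance is not excluded. The same count was 0 with median centring and 14 with array A alone. For late against advanced (179 calls), 3 of 35 splits gave as many and the highest other gave 593. What sets such splits apart was not tested. The other 2 contrasts allow 10 splits, too few for a share under 0.05. Middle against early had 0 calls and advanced against middle 1, with 0 in the highest other split of each. The number of calls also says nothing about which times the arrays belong to.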

How the results depend on the processing

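Slide series, the table with 50 added or quantile normalised, leaving out 30, 40 and 50 min together, and detection by empty or negative control spots alone were chosen after the data were seen. Other window borders are 5 and 10, 15 to 25, 30 to 50 and 60 to 100 min. Gene lists with arrays A and B kept separate were not run. Leaving out 30, 40 and 50 min leaves 1 advanced sample, and slide series 2 holds 1 early sample and no array of 0, 5, 15, 60 or 100 min. A compared window of 1 sample has no spread of its own, so counts of called genes from such fits are not given. What these settings change cannot be put down to slide series or to the omitted times alone. Except where fewer samples or fewer genes entered by construction, the cause was not tested. By the limit from control spots, signal over background was lowest in the dormant sample (22 probes) and at 5 min (158), while by the local background it was lowest at 70 min (3382). With empty spots alone it was lowest at 50 min (3360), and the dormant sample (3549) lay above 5 min (3418). Of the values of single genes and lists from the scanner files under alternatives, 2274 kept their direction and side of the threshold, 776 fell short of it, 83 came to pass it and 31 changed sign. With values of the authors' table, which for single genes are not centred, 17 kept both, 24 fell short and 92 changed sign. Apart from fits with a compared window of 1 sample, counts not given below stayed within 1.5 times the count reported. This does not say that the same genes were called: with the compared windows fitted alone, the 1 gene called for advanced versus middle was rplJ (-2.06) in place of ganS.

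Genes middle versus early numbered 0, and 81 with the authors' table, 140 with the table with 50 added, 398 with the quantile-normalised table. Gene lists middle versus early numbered 10, and 19 with median centring, 18 with quantile-normalised Cy3, 27 with Cy3 scaled to its 75th percentile, 17 with other window borders, 0 with an estimated correlation. Genes advanced versus middle numbered 1, and 0 with median centring, 2 with no background correction, 0 with quantile-normalised Cy3, 0 with Cy3 scaled to its 75th percentile, 101 with the authors' table, 0 with array A alone, 0 with array B alone, 0 with other window borders, 14 with arrays A and B kept separate, 157 with the table with 50 added, 416 with the quantile-normalised table, 0 with slide series as covariate, 0 with slide series 1 alone, 390 with slide series 2 alone, 536 with 30, 40 and 50 min left out. Gene lists advanced versus middle numbered 13, and 21 with the authors' table, 7 with array A alone, 0 with an estimated correlation. Genes late versus advanced numbered 179, and 83 with median centring, 16 with quantile-normalised Cy3, 18 with Cy3 scaled to its 75th percentile, 1 with the authors' table, 56 with array A alone, 101 with array B alone, 372 with no minimum change, 18 with the compared windows fitted alone, 1004 with other window borders, 454 with arrays A and B kept separate, 19 with the table with 50 added, 2 with slide series 1 alone, 1421 with slide series 2 alone. Gene lists late versus advanced numbered 13, and 21 with no background correction, 21 with Cy3 scaled to its 75th percentile, 23 with the authors' table, 23 with the table with 50 added, 0 with an estimated correlation. Genes late versus early numbered 113, and 0 with median centring, 5 with quantile-normalised Cy3, 0 with Cy3 scaled to its 75th percentile, 1010 with the authors' table, 14 with array A alone, 224 with no minimum change, 310 with the compared windows fitted alone, 361 with other window borders, 264 with arrays A and B kept separate, 947 with the table with 50 added, 1053 with the quantile-normalised table, 196 with slide series as covariate, 18 with slide series 1 alone, 669 with slide series 2 alone, 361 with 30, 40 and 50 min left out. Gene lists late versus early numbered 18, and 10 with the authors' table, 9 with probes above background in all 13 germinated samples, 10 with the table with 50 added, 0 with an estimated correlation. Genes late versus vegetative numbered 877, and 2353 with no minimum change. Time-course genes numbered 883, and 1430 with the authors' table, 496 with array A alone, 204 with spline with 2 df, 1542 with spline with 4 df, 1399 with no minimum change, 1690 with the quantile-normalised table. Probes dormant versus 5 min numbered 291, and 128 with median centring, 633 with no background correction, 1055 with quantile-normalised Cy3, 120 with Cy3 scaled to its 75th percentile, 799 with array A alone, 491 with array B alone, 1002 with the authors' table. Transcripts detected in dormant spores numbered 22, and 7 with the stricter percentile of control spots, 3845 with the local background, 3549 with empty spots alone, 9 with negative control spots alone.

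Leaving out each time of the windows in turn gave 0 to 0 genes middle versus early, 8 to 11 gene lists middle versus early, 0 to 198 genes advanced versus middle, 10 to 13 gene lists advanced versus middle, 23 to 1056 genes late versus advanced, 13 to 18 gene lists late versus advanced, 0 to 81 genes late versus early, 15 to 19 gene lists late versus early, 762 to 884 genes late versus vegetative, 316 to 1146 time-course genes. Median shifts that changed sign in this way ranged from -0.71 to 0.0076 for small acid-soluble spore proteins middle versus early, from -0.049 to 0.42 for ribosomal proteins middle versus early, from -0.47 to 0.0025 for iron uptake (Fur) middle versus early, from -0.48 to 0.13 for cell division advanced versus middle, from -0.059 to 0.38 for respiratory chain advanced versus middle, from -0.79 to 0.20 for general stress (SigB) advanced versus middle.

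List shifts below are relative to all genes, while changes of single genes in the authors' table are not centred. Median centring turned the list shifts for middle versus early to 0.054 (iron uptake). Median centring turned the list shifts for late versus early to -0.10 (germination proteins), -0.055 (sporulation regulators and stage genes), 0.43 (aminoacyl-tRNA synthetases), 0.14 (iron uptake). Median centring turned the changes for late versus early to 0.058 (metS). Quantile-normalised Cy3 turned the list shifts for late versus early to -0.017 (germination proteins), 0.13 (aminoacyl-tRNA synthetases). Cy3 scaled to its 75th percentile turned the list shifts for middle versus early to 0.17 (iron uptake). Cy3 scaled to its 75th percentile turned the list shifts for late versus early to -0.20 (germination proteins), -0.11 (sporulation regulators and stage genes), 0.58 (aminoacyl-tRNA synthetases), 0.058 (heat-shock chaperones and proteases), 0.31 (iron uptake). The authors' table turned the list shifts for middle versus early to -0.32 (pyrimidine synthesis), 0.061 (competence), 0.053 (iron uptake), -0.075 (catabolite-repressed degradation). The authors' table turned the list shifts for advanced versus middle to 2.80 (purine synthesis), 1.88 (pyrimidine synthesis), -0.40 (respiratory chain), 1.73 (SigB stress), -0.19 (SPbeta prophage). The authors' table turned the list shifts for late versus advanced to -0.13 (germination proteins), 1.38 (purine synthesis), 1.29 (citric acid cycle), 0.75 (flagella and chemotaxis), 0.39 (PBSX prophage), 0.088 (branched-chain amino acid synthesis), 0.086 (extracellular proteases), 0.24 (catabolite-repressed degradation). The authors' table turned the changes for late versus advanced to -1.45 (yocC), -2.90 (ykwD), -1.77 (ykoJ), -1.46 (yhcU), 0.14 (oppA), 0.78 (rocG), 1.06 (purL), 1.27 (purN), 1.05 (rocE), 1.27 (purQ), 1.16 (purS), -1.24 (clpE), 0.90 (flgE), 0.54 (fliG), 0.81 (fliM), 0.82 (fliL), 0.38 (xkdI), 0.66 (xkdJ), 0.56 (xkdR), 0.11 (ilvD), 0.57 (ilvA), 1.01 (rocD), 1.08 (rbsB). The authors' table turned the list shifts for late versus early to -0.45 (germination proteins), -0.20 (sporulation regulators and stage genes), 1.39 (aminoacyl-tRNA synthetases), 3.53 (purine synthesis), 2.93 (citric acid cycle), -0.33 (respiratory chain), 0.40 (heat-shock chaperones and proteases), 1.29 (flagella and chemotaxis), 0.45 (PBSX prophage), -0.47 (SOS and DNA repair), 0.21 (iron uptake), 0.91 (branched-chain amino acid synthesis), 1.45 (sulfur amino acid synthesis). The authors' table turned the changes for late versus early to -2.50 (yocC), -2.01 (yocD), -0.49 (queE), -0.68 (queF), -1.40 (yhcU), -0.53 (ypmS), -0.67 (ypmT), -0.75 (ypzK), -0.45 (yojO), -0.92 (dinF), 4.57 (purL), 5.12 (purN), 4.41 (purQ), 4.77 (purH), 4.57 (purM), 4.28 (purS), 4.28 (purF), 4.39 (purC), 4.51 (sumT), 4.70 (purD), 5.00 (cysC), 1.25 (purA), 3.02 (serS), 3.53 (gatC), 3.85 (gatA), 2.76 (metS), 2.36 (groES), 1.26 (groEL), 0.43 (mcsA), 2.13 (htpG), 3.60 (comS), 2.75 (nucA), -0.79 (comEB), 1.44 (comGG), -0.33 (nfo), -0.46 (uvrA), -1.15 (uvrB), 4.07 (cysP), 4.62 (sat). Other window borders turned the list shifts for advanced versus middle to 0.12 (cell division), -0.0056 (respiratory chain), 0.23 (SigB stress). Slide series as covariate turned the list shifts for middle versus early to -0.054 (SigB stress), -0.080 (catabolite-repressed degradation). Slide series 2 alone, which holds 1 early sample, turned the list shifts for middle versus early to -0.023 (ribosomal proteins), -0.17 (SigB stress), 0.022 (competence). Slide series 2 alone turned the list shifts for advanced versus middle to 0.14 (cell division), -0.098 (respiratory chain), 0.15 (SigB stress).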

Other observations

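The values of this part were chosen after the data were seen, and they carry no test. The first of them are medians of gene groups in the authors' value table. The median of 53 ribosomal proteins was 291 at 5 min and 24577 at 10 min. The SigB general stress list had medians of 737 at 30 min, 7206 at 50 min and 1333 at 70 min. The purine synthesis median was 2598 at 10 min, 377 at 20 min and 17738 at 60 min. Pyrimidine synthesis had 2 highs, 10498 at 10 min and 17176 at 50 min, with 1910 at 25 min and 2311 at 70 min between and after them, and again 10254 at 90 min. The columns for 50 and 60 min were no arrays' best match, so these highs have no matched arrays.

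In the scanner files the citric acid cycle median was 2.98 and 2.96 in arrays filed under 40 and 50 min and -3.16 in those filed under 60 min. This was the largest step between neighbouring filed times of the groups plotted. The arrays filed under 40 and 50 min are among those with no counterpart in the table. Those filed under 60 min matched the table's 10 min (rho 0.998), so the step need not be one between neighbouring times.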
